A study of Homo sapiens with 6 samples.

How the data were processed

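RNA from 6 libraries of HOK-16B cells, 3 treated with CBD and 3 with vehicle, was sequenced in paired-end mode, per the labels' protocols, after column extraction of total RNA. The cell line tag and title give HOK-16B for each sample, while the free-text description numbers the line HOK-16B to HOK-21B over the 6 samples; 1 line was taken for all. Groups were taken from the treatment label, and replicate numbers from the titles. A single table held one value per gene and library for 58735 genes. Its values are FPKM, deposited by the authors and, per the file headers, given per library with no pooling. The submitters' processing notes name HISAT2 2.0.5 and featureCounts 1.5.0-p3, an aligner and a read counter. Genome build, annotation, strand setting and any filter were not given in the sources used here. FPKM divides each gene's fragments by gene length and by the library's total, so an abundant class that changes shifts all other genes, and GC-dependent yield is not corrected.

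All 58735 gene identifiers were found in GENCODE release 29 (GRCh38), and 58207 also had a current symbol in a name table. Multiplying each FPKM by the exon-union length in that release and by one scaling factor per library gave whole fragments for 100% of the values at a tolerance of 0.01 of a read. The totals were therefore recovered: 21200871, 20271670 and 18213784 fragments in vehicle replicates 1 to 3 and 22158614, 21470824 and 19010494 in CBD replicates 1 to 3. A floor of 3 reads corresponds to 0.126 to 0.153 FPKM for a gene of 1 kb, a limit that covers counting error only. Coordinates are GENCODE 29 gene spans. Replicates were compared by a chi-square statistic on recovered reads. Per gene it was 4.75 to 18.4 among vehicle pairs and 3.09 to 3.22 among CBD pairs, all above sampling noise. No library was therefore taken as a second run of another. The statistic covers counting error only, so it cannot tell repeat preparations of one culture from separate cultures.

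Differences were computed on log2(FPKM + 1) for the 12517 genes with a mean FPKM of at least 1 over all 6 libraries. The model was limma 3.58.1 in R 4.3.3, with group as the only term and an intensity trend in the variance prior (prior degrees of freedom 3.00, residual 4), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Exact permutation tests of single values enumerated all splits into 3 and 3 and were two-sided. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry; 37 of 41 lists had at least 5 tested members, and Benjamini-Hochberg adjustment ran over those 37. The lists held 1046 genes, of which 1044 were matched by symbol. Means are given with SD and fitted differences with SE.

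The design, the lists, a panel of 25 genes, 17 alternative settings and the rule for named genes were fixed before the data were examined. The rule names the 10 called genes with the largest rise and the 10 with the largest fall whose groups do not overlap, the panel, and for each described list up to 4 members with the smallest adjusted p. A panel gene is not reported here. From these and the remaining called genes a selection is described, and 1 called pseudogene on a sex chromosome is counted without a level. SMN2 was added to the text because it is the near-identical copy of SMN1. Alternatives covered the pseudocount, the filter on low values, scaling, variance prior, weights, the replicate block and leaving out each library. A further 6 were chosen after seeing the data: limma-voom on the recovered reads, library quality weights, protein-coding genes only, and removal of a loess trend (span 0.3) in GC content, in GC content and length, and in GC content without vehicle replicate 1. GC content came from the annotated transcripts and was available for 12510 of the tested genes.

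The pipeline was tested on simulated data with the real genes, means and library sizes for the comparison of CBD against vehicle. Of 97 genes changed by 1.5-fold 84.5% were called, and of 97 changed by 2-fold 100%, while 16 unchanged genes (8.21% of the calls) were called among 12520 tested. The list test called a list of 30 genes changed by 1.2-fold and 0 of 19 unchanged lists by camera. Simulated genes were drawn independently, with the same dispersion for all and no GC trend. These figures therefore do not cover GC differences between libraries or correlated genes, and the real lists had estimated correlations up to 0.36 (mitosis and G2/M). As strand setting is not known here, reads of a gene and of one that overlaps it cannot be told apart; 19 of the 44 called genes overlap another annotated gene, and 9 overlap one with a mean FPKM of at least 1 (RNU7-75P, TP73, ABHD8, HSPA8, DLK2, GNL3, THBS1, TINCR and LRP1). Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.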

Results

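Gene expression was measured by paired-end sequencing of total RNA from cells labelled HOK-16B, an immortalized line of human oral keratinocytes, the epithelial cells that line the mouth. According to the series description the cells received an inflammatory stimulus after pretreatment with cannabidiol (CBD), a non-intoxicating compound of the cannabis plant, or with vehicle alone. There were 3 CBD and 3 vehicle libraries, and the labels name neither the stimulus nor the dose or time. No unstimulated group was analysed here, so every value below is CBD against vehicle in stimulated cells. The fragments counted in genes, recovered from the FPKM values (fragments per kilobase of transcript, scaled to library depth), numbered 21200871, 20271670 and 18213784 in vehicle replicates 1 to 3 and 22158614, 21470824 and 19010494 in CBD replicates 1 to 3. Between 12525 and 12671 genes per library had an FPKM of at least 1, and transcripts of the mitochondrial genome took 4.34% to 5.10% of the fragments. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

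The comparison asked how CBD pretreatment altered the transcriptome of stimulated keratinocytes. Genes that rose with CBD included CLIC3, an intracellular chloride channel protein, from 7.03 ± 0.713 to 14.0 ± 0.753 FPKM (SD, n = 3), and CDKN1C, an inhibitor of cyclin-dependent kinases, from 17.9 ± 1.93 to 32.1 ± 1.70 FPKM. NDRG1, a gene known to be induced by hypoxia and cell stress, rose from 16.5 ± 0.764 to 24.8 ± 0.336 FPKM. The inflammatory cytokine gene IL1A fell from 11.9 ± 1.76 to 6.20 ± 0.131 FPKM, and F3, which encodes tissue factor, the starter of blood coagulation, fell from 16.4 ± 0.420 to 10.3 ± 0.486 FPKM. In all, 32 genes were higher and 12 lower with CBD among 12517 tested (limma, Benjamini-Hochberg adjusted p under 0.05), with adjusted p from 0.0282 to 0.0490.

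Changes were small. On the log2(FPKM + 1) scale, which understates the change of low genes, rises ran from 0.33 to 0.90 and falls from -0.39 to -1.19. CLIC3 on chromosome 9 (136994635 to 136996803, GENCODE 29 gene span on GRCh38) rose by 0.90 ± 0.08 (SE; limma adjusted p = 0.0282), and CDKN1C on chromosome 11 (2883213 to 2885773) by 0.81 ± 0.08 (limma adjusted p = 0.0452). The pro-apoptotic BCL2-family gene BMF rose by 0.63 ± 0.07, from 2.11 ± 0.230 to 3.81 ± 0.0907 FPKM. KRT19, a keratin of simple epithelia, rose from 26.0 ± 2.03 to 39.5 ± 1.75 FPKM, and ALDH3A1, an aldehyde dehydrogenase, from 1.90 ± 0.184 to 3.26 ± 0.179 FPKM. ALKBH7, a mitochondrial dioxygenase, rose by 0.59, the poly(A) polymerase gene TENT5B by 0.56, the LIM-domain gene CRIP2 by 0.55, and DUX4L50 by 0.58, a pseudogene whose reads may be shared with near-identical copies. NDRG1 on chromosome 8 (133237171 to 133302022) rose by 0.56 ± 0.05 (limma adjusted p = 0.0301). The small heat shock protein gene HSPB1 rose from 653 ± 36.9 to 908 ± 12.4 FPKM, and the AP-1 subunit gene JUND from 36.7 ± 2.82 to 53.5 ± 1.93 FPKM. The keratinocyte transcription factor gene KLF4 rose from 12.8 ± 0.413 to 16.6 ± 0.404 FPKM, and TP73, a relative of p53, from 3.72 ± 0.227 to 5.89 ± 0.213 FPKM. TINCR, a transcript linked to epidermal differentiation, rose by 0.53, and LGALS7, a galectin gene of stratified epithelia that shares sequence with LGALS7B, by 0.51.

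Among the falls, IL1A on chromosome 2 (112773915 to 112784590) changed by -0.83 ± 0.10 (SE; limma adjusted p = 0.0452) and F3 on chromosome 1 (94529225 to 94541800) by -0.62 ± 0.05 (limma adjusted p = 0.0282). THBS1, which encodes the matrix protein thrombospondin-1, fell from 63.1 ± 5.11 to 39.9 ± 3.70 FPKM, and FOSL1, an AP-1 subunit gene, from 4.94 ± 0.182 to 2.91 ± 0.407 FPKM. The nucleolar helicase gene DDX21 fell from 52.9 ± 3.86 to 36.4 ± 2.01 FPKM, and GNL3, which encodes nucleostemin, from 30.7 ± 1.5 to 23.1 ± 0.467 FPKM. The constitutive chaperone gene HSPA8 fell from 216 ± 13.6 to 152 ± 4.41 FPKM. SMN1, needed for assembly of spliceosomal particles, fell from 9.20 ± 2.04 to 3.44 ± 0.599 FPKM, a log2 change of -1.19 ± 0.16. Its near-identical copy SMN2 stood at 2.99 ± 0.187 and 2.96 ± 0.409 FPKM, and how reads were divided between the copies is uncertain. The long noncoding RNA SFTA1P fell from 1.96 ± 0.0538 to 0.602 ± 0.209 FPKM. The calls of RNU7-75P and MIR4324 rested on 3 to 4 reads per vehicle library against 1 per CBD library, and on 4 to 6 against 2. Neither passed limma-voom on the recovered reads (adjusted p = 0.103 and 0.182). RNU7-75P lies inside NUP155 and MIR4324 inside SLC6A16.

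**Figure D1:**
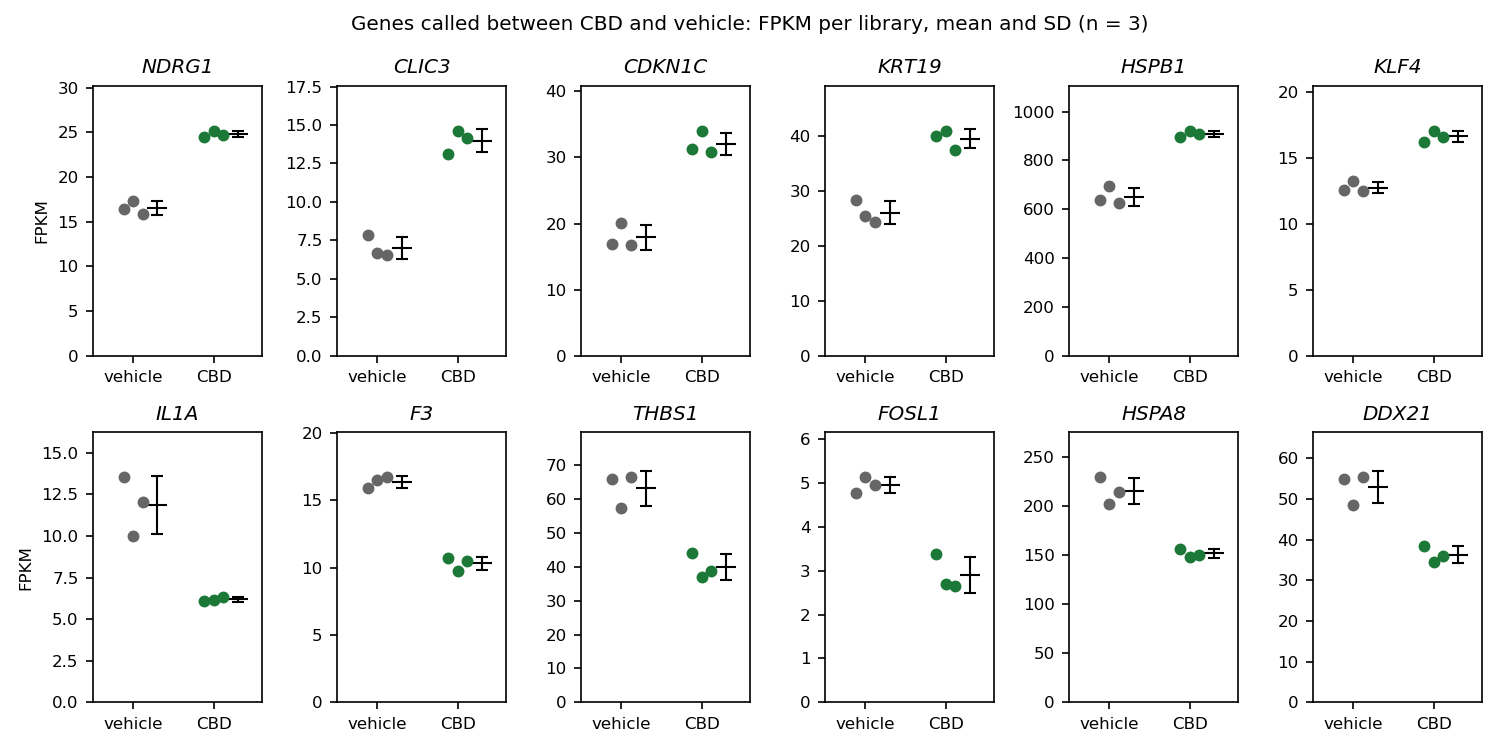
FPKM (vertical axes, from 0) of 12 called genes in each of the 6 libraries, vehicle in grey and CBD in green, with the group mean and SD (n = 3) as a bar. In each of these genes the 3 CBD libraries lie apart from the 3 vehicle libraries; CLIC3 has means of 7.03 and 14.0 FPKM and IL1A of 11.9 and 6.20 FPKM.

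Of the 44 called genes, 39 were protein-coding, and 2, SMN1 and RNU7-75P, changed by 2-fold or more on the log2(FPKM + 1) scale, both downward. By the ratio of mean FPKM 5 called genes fell and 0 rose by 2-fold or more. On the log2 scale 0 genes rose by 2-fold by limma, against 16 at an unadjusted p under 0.05 and 13 with limma-voom on the recovered reads. An unadjusted p under 0.05 was found for 3926 genes by limma, 1922 higher and 2004 lower. In 5092 genes (40.7%, where chance gives each gene 10%) the 3 CBD values did not overlap the 3 vehicle values. Genes are not independent, so a difference shared by many of them can raise that share, which is no test of CBD. With 3 libraries per group the smallest two-sided exact permutation p is 0.1, which each of the 44 called genes reached. Counts moved widely, as limma-voom gave 909 higher and 836 lower, rescaling every library to the same sum gave 2 and 2, and the GC correction described with the library comparison gave 3 and 2. Without vehicle replicate 1 there were 59 higher and 22 lower, without vehicle replicate 2 1267 and 1084, without CBD replicate 3 1 and 0, and 0 and 0 without vehicle replicate 3, CBD replicate 1 or CBD replicate 2 by limma, although 2943, 2594 and 2454 genes then still had an unadjusted p under 0.05.

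The libraries differed in GC content along with the groups. The mean transcript GC content per counted fragment was 48.9%, 49.7% and 49.3% in vehicle replicates 1 to 3 and 50.1% in each CBD library, or 49.3% ± 0.396 against 50.1% ± 0.0430 (SD, n = 3; exact permutation p = 0.1, the smallest possible). Across genes, which are not independent replicates, the log2 difference rose with transcript GC content (Spearman 0.66, and 0.57 without vehicle replicate 1), from a median of -0.16 in the GC-poorest decile to 0.24 in the GC-richest. The called genes that rose had a median GC content of 61.8% and those that fell 43.6%, against 48.1% for all tested genes. With a GC trend removed from each library, the 44 called genes kept their direction and a median share of 0.682 of their log2 change. The lower quartile of that share was 0.585, and some genes kept less. JUND, with a GC content of 69.7%, went from 0.53 to 0.20 with the trend removed, and HSPB1 from 0.48 to 0.24. CDKN1C, NDRG1, IL1A and RNU7-75P, 4 in all, were then still called, and 43 had an unadjusted p under 0.05. Vehicle replicate 1 stood farthest from the others, with a first principal component score of -25.1 (47.7% of the variance) against -9.36 and 0.739 for the other vehicle libraries and 10.3 to 12.7 for CBD. Correlations of log2 values between libraries were 0.990 to 0.991 within CBD, 0.979 to 0.988 within vehicle and 0.971 to 0.988 between the groups. Vehicle replicate 2 correlated with the CBD libraries at 0.987 to 0.988, about as highly as with its own group (0.979 and 0.988).

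**Figure D2:**
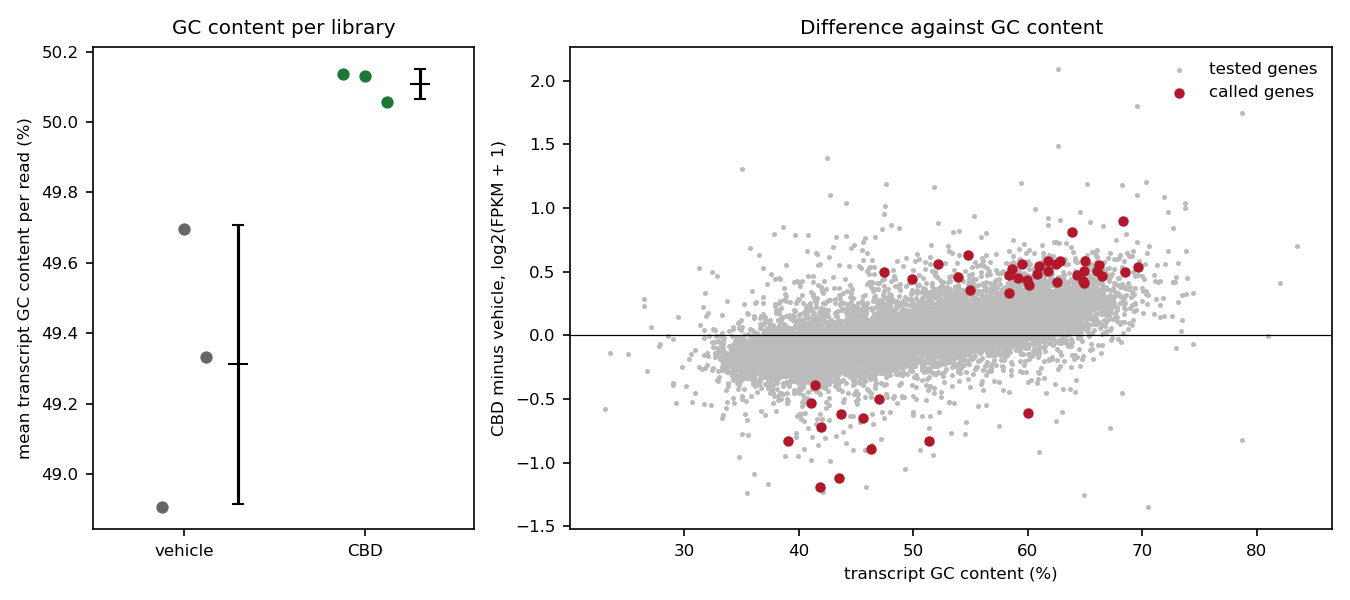
Left, mean transcript GC content per counted fragment (percent; the axis does not start at 0) in each library, with group mean and SD (n = 3), 49.3% in vehicle and 50.1% in CBD. Right, log2 difference of CBD minus vehicle for each tested gene against its transcript GC content, with the 44 called genes in red; the difference rises with GC content.

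Among inflammatory genes, IL1A was called and most others were not. In the list of inflammatory cytokines and chemokines, 20 members were tested. IL1A fell, the other 19 did not pass over all genes, and adjusted over the list alone 1 rose and 6 fell. Of all tested genes 31.4% had an unadjusted p under 0.05 by limma. Counts adjusted over a list alone, here and below, therefore do not set a list apart from other genes. CXCL14, a chemokine of resting epithelia, stood at 52.9 ± 5.98 and 78.6 ± 10.4 FPKM (limma adjusted p = 0.0604), CXCL10, an interferon-induced chemokine, at 25 ± 3.48 and 17.9 ± 1.94 FPKM (0.0763), and TGFA, a growth factor, at 4.95 ± 0.231 and 3.82 ± 0.509 FPKM (0.0836). IL1B had 4.32 ± 0.508 and 3.46 ± 0.0519 FPKM, a log2 difference of -0.25 (limma adjusted p = 0.0933; 95% interval -0.43 to -0.07). IL6 had 1.67 ± 0.290 and 1.18 ± 0.190 FPKM (adjusted p = 0.139), CXCL8 1.51 ± 0.140 and 1.19 ± 0.206 FPKM (0.222), and CCL20 2.53 ± 0.0608 and 1.93 ± 0.403 FPKM (0.129), all by limma and none called. TNF and PTGS2 lay below the level tested, at 0.120 ± 0.0864 and 0.108 ± 0.0507 FPKM and at 0.273 ± 0.0322 and 0.292 ± 0.0626 FPKM. The mean log2 difference of the cytokine list was -0.11 (camera adjusted p = 0.228), while fry, which tests a list's own direction without comparing it with other genes, gave an adjusted p of 0.00265. The list's median GC content was 45.6%, and its mean difference -0.05 with the GC trend removed.

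Of 26 tested target and feedback genes of NF-kB, the main transcription factor of inflammatory signalling, 0 rose and 0 fell over all genes by limma, and adjusted over the list alone 1 rose and 0 fell. Their mean difference was -0.0028 and their median 0.0073 (camera adjusted p = 0.975), the mean turning to 0.01 with median-ratio scaling. The inhibitor gene NFKBIA had 86.5 ± 11.8 and 101 ± 2.31 FPKM (limma adjusted p = 0.159), TNFAIP2 15.0 ± 0.842 and 18.3 ± 0.597 (0.0605), IRAK2 2.28 ± 0.255 and 1.66 ± 0.141 (0.0855), and BIRC3 57.8 ± 4.74 and 49.3 ± 1.49 (0.0916). Among 25 AP-1 and immediate early genes, JUND and KLF4 rose and FOSL1 fell, and adjusted over the list alone 11 rose and 6 fell. FOS stood at 59.7 ± 5.08 and 80.2 ± 3.92 FPKM (limma adjusted p = 0.0552). The AP-1 list as a whole did not pass (mean 0.11; camera adjusted p = 0.165), though it did at a mean FPKM of at least 5 (0.0175; range over alternatives 0.0175 to 0.344).

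**Figure D3:**
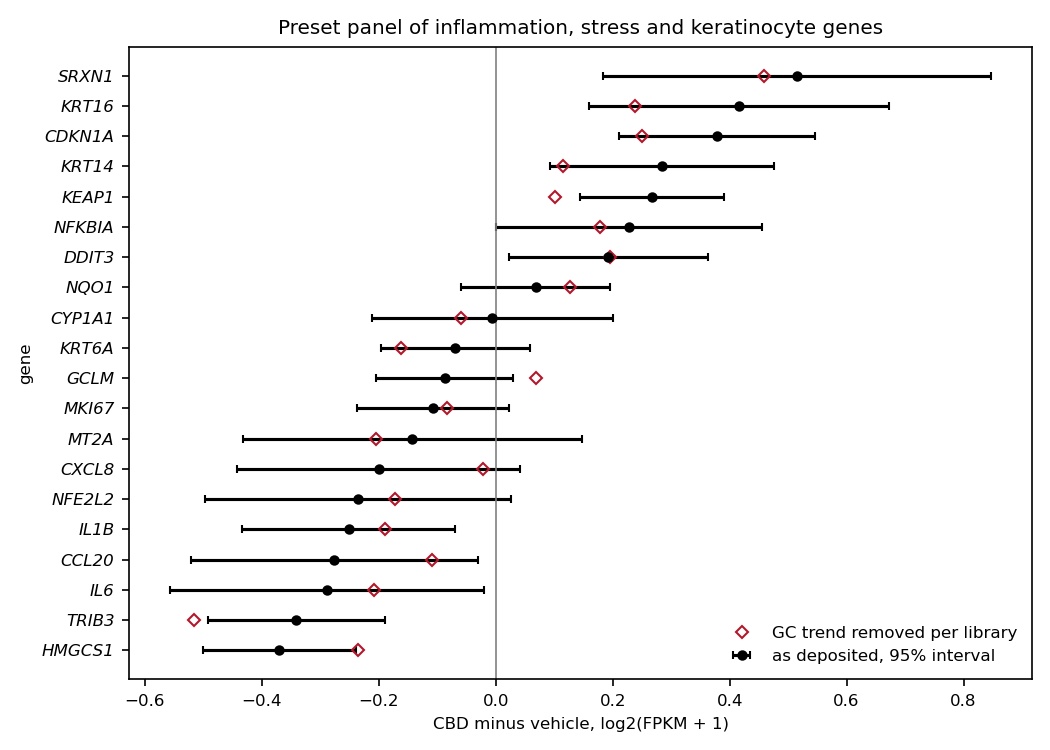
Log2 difference of CBD minus vehicle (horizontal axis) for tested genes of a panel fixed before the data were examined, with 95% intervals from limma, and the same difference with the GC trend removed per library (open diamonds). None of these genes was called; SRXN1 has the highest difference, 0.52, and HMGCS1 the lowest, -0.37.

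Type I interferon response genes were lower as a list. The mean over 35 members was -0.10 and 26 lay below 0 (camera adjusted p = 0.0201; adjusted p = 0.659 with an estimated correlation). None passed over all genes by limma, and adjusted over the list alone 1 rose and 10 fell. The list means per library overlapped between groups, at 5.95 in CBD replicate 2 and 5.94 in vehicle replicate 2 (exact permutation p = 0.2). RIGI and IFIH1, cytosolic sensors of viral RNA, had 54.3 ± 8.30 and 36.9 ± 2.22 FPKM (limma adjusted p = 0.0604) and 41.0 ± 3.91 and 31.8 ± 0.767 FPKM (0.0605), and IFIT3 had 134 ± 11.7 and 97.5 ± 7.52 FPKM (0.0574). IFI6, an interferon-induced mitochondrial protein gene, lay the other way, at 648 ± 87.6 and 965 ± 54.6 FPKM (0.0553). The call did not pass without vehicle replicate 3 (camera adjusted p = 0.0629) or CBD replicate 3 (0.0638), the range over 23 alternatives being 0.000478 to 0.0638. With the GC trend removed the interferon mean was -0.08 and the call held. Antigen presentation genes were higher as a list of 18 (mean 0.14, 15 above 0; camera adjusted p = 0.0201; adjusted p = 0.569 with an estimated correlation), with 0 called over all genes and, adjusted over the list alone, 3 up and 1 down. PSMB9, an immunoproteasome subunit, had 21.7 ± 1.14 and 29.2 ± 2.40 FPKM (limma adjusted p = 0.0553), HLA-C, whose reads can be shared with other HLA genes, 270 ± 32.8 and 349 ± 16.3 (0.0709), and IRF1 5.77 ± 0.450 and 7.06 ± 0.168 (0.0718). The GTPase gene GBP1 had 30.9 ± 1.08 and 25.4 ± 1.88 (0.0670). The antigen presentation list had a median GC content of 56.2%, and with the GC trend removed its mean was 0.08 and its call ended. That call also ended without vehicle replicate 3 (camera adjusted p = 0.0533) or CBD replicate 2 (0.0741), and after quantile normalization (0.0549), within a range over alternatives of 0.0102 to 0.105.

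Targets of NRF2, the transcription factor of the antioxidant response, were higher as a list of 33 (mean 0.11, 24 above 0; camera adjusted p = 0.0201; adjusted p = 0.569 with an estimated correlation). ALDH3A1 rose and the other 32 did not pass over all genes; adjusted over the list alone 8 rose and 1 fell. AKR1B10, an aldo-keto reductase, had 4.09 ± 0.327 and 5.65 ± 0.502 FPKM (limma adjusted p = 0.0604), the pentose phosphate enzyme gene TKT 58.8 ± 0.705 and 66.2 ± 0.493 (0.0702), and BLVRB, a biliverdin reductase, 51.0 ± 3.21 and 62.2 ± 4.41 (0.0736). The sulfiredoxin gene SRXN1 had 1.73 ± 0.457 and 2.88 ± 0.415 FPKM (0.0809), NQO1 24.8 ± 1.29 and 26.0 ± 0.765 (0.404), and GCLM 6.67 ± 0.262 and 6.21 ± 0.126 (0.262). NFE2L2, which encodes NRF2, had 28.0 ± 4.91 and 23.4 ± 0.521 (0.192), and its repressor KEAP1 30.1 ± 1.30 and 36.5 ± 1.21 (0.0585). GCLM lay below 0 as deposited (-0.09) and above 0 with the GC trend removed (0.07). HMOX1, the heme oxygenase gene often used as an NRF2 readout, was below the level tested, at 0.666 ± 0.198 and 1.08 ± 0.155 FPKM (24, 41 and 37 against 71, 60 and 46 reads; exact permutation p = 0.1; limma adjusted p = 0.321 without the filter on low values). With the GC trend removed the NRF2 list kept a mean of 0.09 and its call. The call did not pass without vehicle replicate 2 (camera adjusted p = 0.0660) or CBD replicate 2 (0.0693), at a mean FPKM of at least 5 (0.114), after quantile normalization (0.0662) or with library weights (0.0993), the range over 23 alternatives being 0.00517 to 0.114.

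Called heat shock genes went both ways. HSPB1 rose and HSPA8 fell among 22 tested members, and adjusted over the list alone 4 rose and 9 fell. The mitochondrial chaperonin gene HSPD1 had 136 ± 3.90 and 113 ± 2.07 FPKM (limma adjusted p = 0.0552), and DNAJA1 77.1 ± 2.03 and 64.7 ± 0.735 (0.0553). The list's mean was -0.06, with 14 members below 0 (camera adjusted p = 0.228; fry adjusted p = 0.0143). Its mean was -0.07 with the GC trend removed, where it passed as lower (camera adjusted p = 0.0250; range over alternatives 0.00360 to 0.399). In the integrated stress response list under ATF4, 0 of 31 members passed by limma over all genes, and adjusted over the list alone 4 rose and 5 fell (camera adjusted p = 0.653). There the glycine transporter gene SLC6A9 had 5.28 ± 0.515 and 7.79 ± 0.209 FPKM (limma adjusted p = 0.0502), and TRIB3 9.41 ± 0.769 and 7.21 ± 0.145 (0.0574). XPOT had 29.2 ± 2.51 and 23.6 ± 0.369 (0.0636) and DDIT3 5.75 ± 0.506 and 6.71 ± 0.404 (0.128). Of the remaining stress panel, MT2A, a metal-binding metallothionein gene, had 876 ± 162 and 785 ± 26.8 FPKM (0.447), and CYP1A1, an aryl hydrocarbon receptor target, 4.0 ± 0.554 and 3.96 ± 0.187 (0.968).

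Cholesterol genes were tested as efflux and as synthesis lists. The efflux list of 11 LXR targets was higher (mean 0.14, 8 above 0; camera adjusted p = 0.0201; adjusted p = 0.569 with an estimated correlation), with 0 called over all genes by limma and, adjusted over the list alone, 5 up and 0 down. APOE, a lipid carrier, had 50.0 ± 4.33 and 65.4 ± 4.37 FPKM (limma adjusted p = 0.0604), and SREBF1, a transcription factor of lipid synthesis, 55.6 ± 4.10 and 66.8 ± 1.92 (0.0690). NR1H2, which encodes LXR beta, had 15.6 ± 1.51 and 18.9 ± 0.616 (0.0793) and PLTP 79.2 ± 2.84 and 88.0 ± 0.544 (0.0930). With the GC trend removed the efflux mean was 0.07 and the call ended, as it did without vehicle replicate 3 (camera adjusted p = 0.0629) or CBD replicate 2 (0.0740) and after quantile normalization (0.0549; range over alternatives 0.00147 to 0.115). APOE, with a GC content of 68.5%, went from a difference of 0.38 to 0.07 with that trend removed. Biosynthesis and uptake genes did not pass (25 members, mean 0.02, and -0.01 after quantile normalization; camera adjusted p = 0.914), with 0 called over all genes by limma and, adjusted over the list alone, 7 up and 9 down. HMGCS1, an early enzyme of the pathway, had 114 ± 6.15 and 87.7 ± 2.37 FPKM (limma adjusted p = 0.0502), and ACAT2 37.4 ± 1.68 and 31.5 ± 0.638 (0.0605). TM7SF2 had 3.93 ± 0.180 and 5.49 ± 0.329 (0.0531) and CYP51A1 2.76 ± 0.741 and 4.80 ± 0.176 (0.0608). Autophagy and lysosome genes were higher as a list of 32 (mean 0.09, 23 above 0; camera adjusted p = 0.0361; adjusted p = 0.569 with an estimated correlation), with 0 called over all genes and, adjusted over the list alone, 3 up and 0 down. The autophagy kinase gene ULK1 had 9.12 ± 1.10 and 13.1 ± 0.490 FPKM (limma adjusted p = 0.0552), the lysosomal channel gene MCOLN1 5.11 ± 0.284 and 6.36 ± 0.184 (0.0605), and GABARAPL1 10.3 ± 1.22 and 12.7 ± 0.218 (0.0852). That call ended with the GC trend removed, where the mean was 0.06. It also ended without vehicle replicate 2, vehicle replicate 3 or CBD replicate 2 (camera adjusted p = 0.0696, 0.0629 and 0.0741; range over alternatives 0.0105 to 0.0990). Quantile normalization (0.0549), equal library sums (0.0552) and library weights (0.0646) ended it too.

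Ribosomal and mitotic genes went opposite ways. The 41 cytosolic ribosomal protein genes were higher (mean 0.11, 30 above 0; camera adjusted p = 0.00504; adjusted p = 0.569 with an estimated correlation), though 0 members passed by limma either over all genes or adjusted over the list alone. RPS12 had 442 ± 18.9 and 525 ± 21.6 FPKM (limma adjusted p = 0.0670), RPL35 294 ± 12.4 and 356 ± 19.5 (0.0636) and RPS3 166 ± 10.5 and 198 ± 8.80 (0.0718). With the GC trend removed the ribosomal mean was 0.09 and the call held; after quantile normalization it ended (camera adjusted p = 0.103, range over alternatives 3.5e-06 to 0.103). The 34 genes of mitosis and the G2/M transition were lower (mean -0.11, 26 below 0; camera adjusted p = 0.0201; adjusted p = 0.687 with an estimated correlation), with 0 called by limma over all genes or adjusted over the list alone. The kinetochore genes NDC80 and CENPE had 14.0 ± 0.906 and 11.9 ± 0.148 FPKM (limma adjusted p = 0.0746) and 10.3 ± 1.41 and 7.96 ± 0.148 (0.0778), and the spindle gene TPX2 81.9 ± 5.40 and 70.6 ± 0.922 (0.0833). The proliferation marker MKI67 had 40.9 ± 2.06 and 37.9 ± 1.35 FPKM (0.225). The mitotic means per library overlapped between groups, at 4.65 in CBD replicate 1 and 4.63 in vehicle replicate 2 (exact permutation p = 0.2). The mitotic list had a median GC content of 42.9%. Its mean was -0.04 with the GC trend removed and the call ended, as it did without vehicle replicate 3 (camera adjusted p = 0.0629) or CBD replicate 2 (0.0740; range over alternatives 0.000509 to 0.214). Replication and G1/S genes did not pass as deposited (32 members, mean -0.05; camera adjusted p = 0.162), with 0 called over all genes by limma and, adjusted over the list alone, 2 up and 7 down. The list passed as lower with the GC trend removed (mean -0.05; camera adjusted p = 0.0214) and without the filter on low values (0.0168; range over alternatives 0.0168 to 0.245). CDT1 had 26.2 ± 2.23 and 34.6 ± 1.26 FPKM (limma adjusted p = 0.0557), and MCM10 9.42 ± 0.642 and 7.79 ± 0.328 (0.0734).

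Keratinocyte genes were tested in 3 lists, none of which passed camera as deposited. Of 45 terminal differentiation genes, 13 were high enough to test and 6 were at 0 in every library, IVL (involucrin) among them with 0 reads in each, which allows up to 3 reads per library. The 13 had a mean difference of 0.15 (camera adjusted p = 0.0777), 0 were called over all genes by limma, and adjusted over the list alone 3 rose and 0 fell. The differentiation list had a mean of 0.11 with the GC trend removed and passed as higher there (camera adjusted p = 0.0214; range 0.0214 to 0.404 over 23 alternatives, of which 4 passed). The cornified envelope genes PPL and EVPL had 28.0 ± 2.68 and 37.1 ± 0.232 FPKM (limma adjusted p = 0.0557) and 16.9 ± 2.27 and 22.2 ± 0.928 (0.0725), and the suprabasal keratin gene KRT10 5.18 ± 0.212 and 7.65 ± 1.55 (0.0811). In the basal and hemidesmosome list (21 members, camera adjusted p = 0.618) 0 passed over all genes, and adjusted over the list alone 3 rose and 4 fell. KRT15 had 4.17 ± 1.06 and 7.93 ± 0.451 FPKM (limma adjusted p = 0.0553), and DST 38.4 ± 2.15 and 31.5 ± 0.441 (0.0574). ITGB1 had 126 ± 6.36 and 108 ± 0.786 (0.0716), and KRT14 2873 ± 265 and 3488 ± 77.3 (0.0855). In the wound-associated list (16 members, mean -0.07, camera adjusted p = 0.170) 0 passed over all genes and, adjusted over the list alone, 1 rose and 6 fell. This list passed by fry (adjusted p = 0.00785) and by camera without the filter on low values (0.0168; range over alternatives 0.0168 to 0.502). The growth factor genes AREG and EREG had 26.7 ± 1.06 and 20.4 ± 1.33 FPKM (limma adjusted p = 0.0539) and 2.44 ± 0.153 and 1.78 ± 0.0724 (0.0636). KRT16 had 116 ± 17.7 and 153 ± 6.81 (0.0763), and KRT6A 1352 ± 24.7 and 1289 ± 41.7 (0.403). Reads of keratin genes can be shared between close paralogs.

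Growth arrest and death genes included SERTAD1, called among 26 p53 targets, which rose from 4.23 ± 0.204 to 6.21 ± 0.421 FPKM. Adjusted over that list alone 11 rose and 4 fell (mean 0.12; camera adjusted p = 0.125). The p53 list passed as higher with the GC trend removed (0.0382) and at a mean FPKM of at least 5 (0.0231; range over alternatives 0.0231 to 0.162). CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, had 53.6 ± 4.22 and 69.8 ± 3.85 FPKM (limma adjusted p = 0.0574), GADD45B 9.51 ± 1.17 and 14.3 ± 1.49 (0.0574) and the death receptor gene FAS 7.60 ± 0.583 and 5.52 ± 0.329 (0.0552). BMF was the called member of 25 apoptosis regulators, of which 5 rose and 0 fell adjusted over the list alone (mean 0.10; camera adjusted p = 0.116). The apoptosis list had a mean of 0.09 with the GC trend removed and passed as higher there (camera adjusted p = 0.00960; range over alternatives 0.00960 to 0.701). BBC3 had 3.24 ± 0.810 and 5.28 ± 0.372 FPKM (limma adjusted p = 0.0668). NDRG1 was the called member of 28 glycolysis and hypoxia genes, of which 5 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.362). The glucose transporter gene SLC2A1 had 41.5 ± 1.95 and 53.4 ± 1.42 FPKM (limma adjusted p = 0.0502). THBS1 was the called member of 26 matrix and TGF-beta target genes, of which 4 rose and 2 fell adjusted over the list alone (mean 0.01, and -0.0061 with equal library sums; camera adjusted p = 0.618). CCN1 had 69.7 ± 4.64 and 88.0 ± 4.29 FPKM (limma adjusted p = 0.0588).

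**Figure D4:**
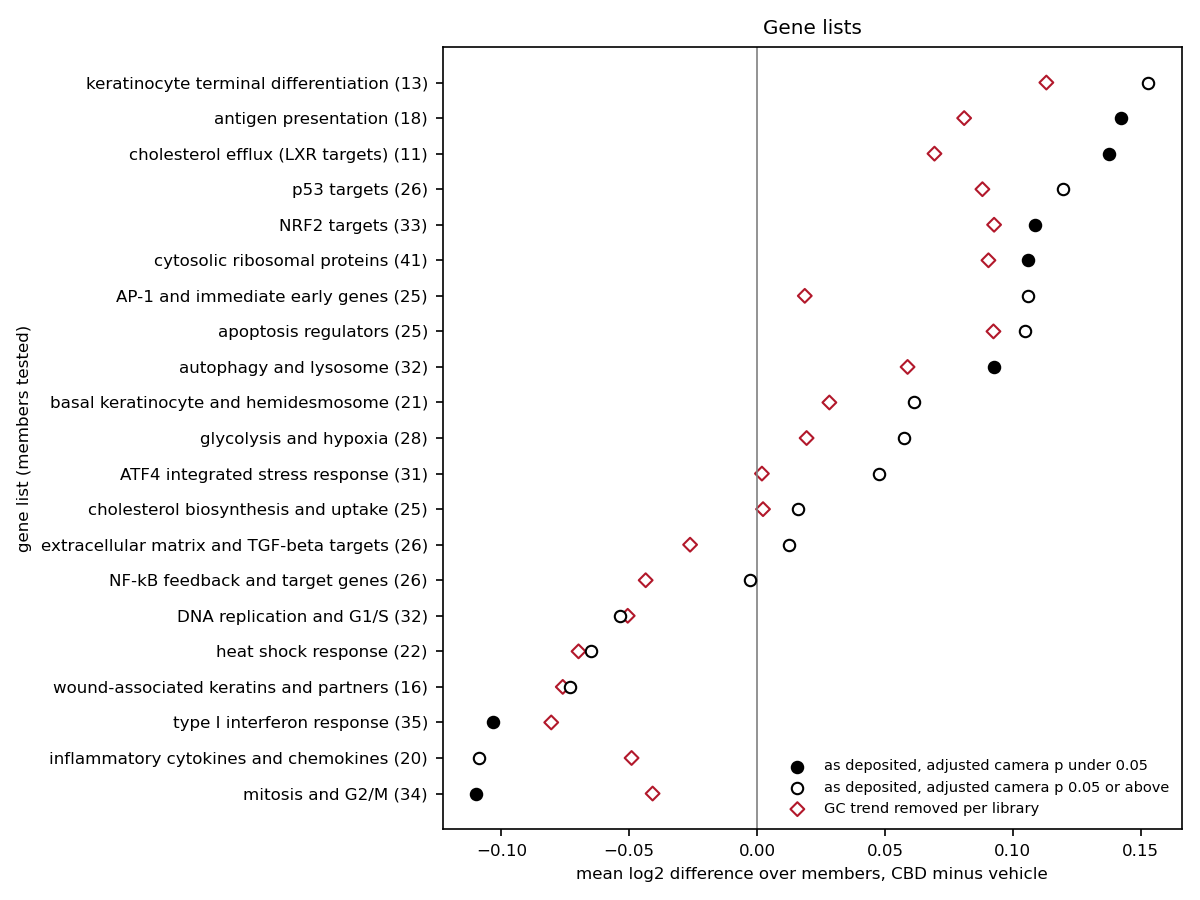
Mean log2 difference of CBD minus vehicle over the tested members of 21 gene lists (number of members in brackets), as deposited (circles, filled where the camera adjusted p was under 0.05) and with the GC trend removed per library (diamonds). The means run from -0.11 for mitosis and G2/M to 0.15 for terminal differentiation, and the correction brings most of them closer to 0.

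In all, 7 of 37 tested lists shifted by camera with a preset correlation of 0.01, 5 up and 2 down, and 0 did with an estimated correlation, where the lowest adjusted p was 0.569. By fry 7 lists passed, of which 2, NRF2 and autophagy, were also camera calls; the others were the cytokine, heat shock, wound-associated, aryl hydrocarbon receptor and unfolded protein response lists. The number by camera was 2 without vehicle replicate 3, 2 without CBD replicate 2 and 2 after quantile normalization. It was 10 with the GC trend removed, of which 3, the ribosomal, NRF2 and interferon lists, were also called as deposited and 7 were not.

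Markers of other cell types were nearly silent. Of 10 fibroblast genes COL1A1 alone reached 1 FPKM, at 7.13 ± 0.416 and 8.69 ± 0.0249 FPKM (limma adjusted p = 0.0608), while COL1A2, its partner chain, had 0.0423 ± 0.0213 and 0.0472 ± 0.0178. Of 9 melanocyte genes PMEL stood at 0.928 ± 0.158 and 1.15 ± 0.101 FPKM (0.316), and of 15 leukocyte genes CSF1R at 1.51 ± 0.176 and 1.94 ± 0.124 (0.121), both by limma and not called. The 8 endothelial genes stayed at or below 0.149 FPKM in both groups, and the leukocyte gene PTPRC was at 0 in vehicle and 0.00157 FPKM in CBD.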

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

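The tests on recovered reads, with library weights, without noncoding genes and with GC or length trends removed were chosen after the result was seen; the other 17 were planned. All 44 called genes kept their direction in each of the 23 alternatives that tested them. How many passed was what moved, for causes not tested. Adjusted p by limma lay near the threshold on both sides, so small changes can carry many genes across it. It was 0.0282 to 0.0490 for the called genes, and 0.0502 for HMGCS1, SLC2A1 and SLC6A9, which were not called. Higher and lower genes numbered 0 and 0 without a filter on low values, 427 and 305 at a mean FPKM of at least 5 and 728 and 587 among protein-coding genes (fewer genes tested in both). They were 2 and 2 rescaled to equal sums, 56 and 17 with median ratios, and 54 and 19 with quantile normalization. They were 0 and 1 with no intensity trend, 95 and 40 with robust priors, 2 and 2 with vooma weights, and 909 and 836 with limma-voom on recovered reads. They were 2711 and 2863 with library weights (0.208 to 5.43; their estimation stopped before convergence), 3 and 2 with GC removed, 5 and 5 with GC and length removed, and 8 and 6 with GC removed and vehicle replicate 1 left out. At the 2-fold limit (0 higher, 2 lower by limma; 16 and 8 at an unadjusted p under 0.05) lower genes numbered 4 at pseudocounts of 0.1 and 0.5. Higher and lower were 0 and 0 without a filter, 4 and 1 at FPKM of at least 5, 0 and 1 rescaled to equal sums, without trend, with vooma or with any GC removal, and 1 and 2 with median ratios or quantiles. They were 2 and 2 with robust priors, 13 and 4 with limma-voom, 39 and 30 with library weights and 1 and 1 among protein-coding genes. Lists shifted numbered 2 with quantile normalization and 0 with an estimated correlation. Leaving out each library gave 0 to 1267 higher, 0 to 1084 lower, 0 to 25 and 0 to 6 by 2-fold, and 2 to 7 lists; vehicle replicate 2 gave the highest counts and vehicle replicate 3, CBD replicate 1 and CBD replicate 2 gave 0 genes by limma, with fewer samples. 

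The replicate block gave 0 higher and 0 lower genes by limma, 0 and 0 by 2-fold, with 3676 at an unadjusted p under 0.05, and 7 lists. Deviations of same-numbered libraries from their group means correlated at -0.0027, 0.052 and 0.024, against -0.052 to 0.028 for libraries of unlike number. Vehicle replicates 2 and 3 correlated best with the CBD library of their own number, and vehicle replicate 1 with CBD replicate 3, at 0.028. Values this small, from 3 libraries per group, cannot decide whether the samples were paired. The labels do not say that the numbers pair the samples, so the pairing was not used.

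Directions that reversed belonged to genes and lists that were not called, and the cause was not tested. GCLM was 0.068 with GC removed, 0.075 with GC and length removed and 0.044 with GC removed and vehicle replicate 1 left out. PLTP was -0.0065 and -0.014 in the first pair of those settings, and TK1 -0.0093 in the second. CYP1A1 was 0.0062 with median ratios, 0.0025 with quantiles and 0.11 with library weights. The NF-kB list mean was 0.045 at FPKM of at least 5 and 0.011 with median ratios. The cholesterol biosynthesis mean was -0.028 at FPKM of at least 5, -0.011 with quantiles and -0.0011 with GC removed without vehicle replicate 1, where the ATF4 mean was -0.022. The matrix list mean was -0.0061 rescaled to equal sums and -0.026, -0.025 and -0.018 in the GC settings. Leaving out each library gave CYP1A1 from -0.076 to 0.079, MT2A from -0.23 to 0.0045, the NF-kB mean from -0.024 to 0.019 and the matrix mean from -0.00076 to 0.028. Depth limits genes such as RNU7-75P and MIR4324, called on 6 reads or fewer per library.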

Other observations

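Nucleolar and YAP target lists, the GC, read-sharing and splitting tests and the corrections they use were chosen after the calls were seen, while the statements of what the YAP, nucleolar and SMN1 tests would show preceded their results. Genes of ribosome assembly in the nucleolus, apart from DDX21 and GNL3, were lower with CBD in a list of 29: 27 had a difference below 0, with a mean of -0.25 log2 and 0 called over all genes by limma. NPM1, which encodes nucleophosmin, had 217 ± 16.4 FPKM in vehicle and 171 ± 4.20 in CBD (SD, n = 3), the snoRNP gene NOP58 29.7 ± 0.906 and 22.7 ± 1.06, WDR43 20.9 ± 2.09 and 15.4 ± 0.532, and POLR1B, a subunit of RNA polymerase I, 12.1 ± 0.807 and 9.06 ± 0.459. FBL and BOP1 lay slightly above 0, at 0.02 and 0.04. Adjusted over the list alone, 23 fell and 0 rose.

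Further lists, none of which passed as deposited, had these values. Nuclear oxidative phosphorylation genes had a mean of 0.08 over 31 members, with 0 called over all genes by limma. Camera gave this list an adjusted p of 0.181, and 0.0214 with the GC trend removed (range 0.0196 to 0.440 over 23 alternatives). The called gene UQCR10, a subunit of complex III that is not among these 31 members, rose from 29.5 ± 1.80 to 42.1 ± 2.08 FPKM. The 15 mitochondrially encoded genes had a mean of -0.07 (camera adjusted p = 0.309). Metallothionein and zinc transport genes had a mean of -0.10 over 7 members (0.362), replication-dependent histone genes 0.16 over 9 (0.181), and candidate receptors of cannabidiol with enzymes of endocannabinoid metabolism -0.01 over 10 (0.914), with 6 above 0 and 4 below, all by camera.

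The first pattern weighed is that GC-rich genes were higher with CBD. The vehicle libraries alone spanned 0.791 percentage points of mean GC content per read, nearly as much as the 0.796 points between the group means, so a GC bias that differs between libraries is a candidate explanation. That vehicle replicate 1 alone carries the pattern is argued against by the correlation across genes of 0.566 that stays without it. Whether the GC trend is the whole cause of the called genes could not be decided. With the trend removed these genes kept a median share of 0.682 of their log2 change. They were chosen on these same libraries for large differences, so much of the change would stay whatever its cause. Most calls ended, and 2418 rather than 3926 genes had an unadjusted p under 0.05 by limma. An effect of CBD on genes that happen to be GC-rich stays open and was not tested separately.

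The second pattern is the fall of DDX21 and GNL3 beside that of F3 and THBS1. A hypothesis of lower nucleolar ribosome assembly may account for the first pair: the other 29 members passed camera with an adjusted p of 6.6e-12 (0.0550 with an estimated correlation), and 29 of 29 lay below 0 with the GC trend removed. The cytosolic ribosomal protein genes went the other way, with a mean of 0.11. A hypothesis of lower YAP and TEAD target genes as a group for the second pair is argued against. The other 17 targets had a mean of 0.04 and a camera adjusted p of 0.211. Members went both ways, 6 lying below 0, with CCN1 at 0.33 and NT5E at -0.50. Adjusted over the YAP list alone 3 rose and 3 fell. Both lists were chosen on these samples and are not independent evidence. Their camera p-values were adjusted over this pair of lists alone. The other lists were adjusted over 37, so the adjusted values cannot be set side by side.

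The third pattern is the fall of SMN1, and of RNU7-75P and MIR4324. A mere shift of reads between SMN1 and SMN2 is argued against by their summed reads, which differed by -0.93 log2 (CBD minus vehicle) while SMN2 alone differed by -0.02. For RNU7-75P and MIR4324, 0 of the 2 passed limma-voom on the recovered reads (adjusted p = 0.103 and 0.182), so counting error of a few reads is a candidate explanation. No biological explanation was tested.

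Splitting the 6 libraries into 3 and 3 in all 10 ways gives too few splits for a share under 0.05. The real split called 44 genes against 2 in the highest other split, and 1 split, the real one, reached that count. It called 2 genes by 2-fold against 2, which 2 splits reached, and shifted 7 lists against 6, which 1 split reached. The split with 2 calls and 6 lists exchanged vehicle replicate 2 with CBD replicate 3.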
